A study of Sus scrofa with 4 samples.

How the data were processed

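The series measured polyadenylated RNA in porcine induced pluripotent stem cells, which are cells reprogrammed to an embryonic-like state, from the Bamei black pig, a Chinese breed. The labels give a development stage of 26.5 days for every library. Short hairpin RNA, which silences a gene by RNA interference, was directed against LIN28A in 2 libraries, and 2 others were negative controls. Groups were taken from the genotype given in the labels. Libraries are called control 1 and 2 and knockdown 1 and 2; the numbers only name a library. The labels do not say whether the 2 knockdown libraries carry the same hairpin or different ones, so their mean and SD may span 2 hairpins; the deposited table averages them in a column headed by the part of their names that they share. Nor do they say whether the 2 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

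Per the labels' protocols, total RNA was extracted with RNAiso Plus, messenger RNA was selected with oligo-dT, fragmented and copied to cDNA, and the amplified libraries were circularised into DNA nanoballs for the BGISEQ-500 sequencer. Per the submitters' processing notes, Bowtie2 and RSEM 1.2.12 were used with the pig genome build Sscrofa11.1. RSEM divides reads that match several genes between them, so values of genes with near-identical copies are estimates. The strandedness, read length and alignment settings are not given in the sources used here. Reads of overlapping and antisense genes may therefore not be separated.

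One deposited table was used, with 16026 genes. Its expected counts, estimated by the authors with RSEM per the submitters' processing notes and the column headers, are not normalised between libraries. Between 8.60% and 12.6% of them per library are not whole numbers, counted exactly on values given to 2 decimals. A second set of columns deposited by the authors is read here as FPKM, fragments per kilobase of transcript scaled to the library total. The header does not name that unit, which was inferred from FZD2, GAS1 and EID1 alone, picked because each spans a single exon. An effective length 200 bases below the gene length was assumed. The median library total implied by their values was then 1.03 to 1.04 times the summed counts in each library. All gene identifiers matched a RefSeq gene table of the same build, which gave chromosomes and positions. A date stood in place of the symbol on 22 rows, and these symbols were restored by identifier; 187 symbols differed from the RefSeq table, and 7 symbols stood on more than 1 row. Protein-coding genes made up 16023 of the rows, and none came from the mitochondrial genome.

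The summed counts were 11847343 and 7125640 in control 1 and 2, and 8061417 and 2400985 in knockdown 1 and 2, a range of 4.93-fold. A count of 3, used as the floor for a gene at 0, corresponds to 0.253, 0.421, 0.372 and 1.25 CPM, counts scaled to the library total, in the same order. Exact Poisson intervals (95%) cover counting error only, since no label names molecular identifiers.

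Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 (R 4.3.3): TMM normalisation, filterByExpr, which left 11967 genes, and the quasi-likelihood test of knockdown against control with no covariate, which leaves 2 residual degrees of freedom per gene plus 3.30 shared across genes. The TMM factors were 1.10, 1.07, 1.07 and 0.798. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Where p was adjusted over a list alone, this was done within that list and not across lists, so it is weaker evidence. Fold changes are log2 of knockdown over control with the standard error from the same fit; FPKM is given as mean ± SD of the 2 libraries of a group. Of 29 lists written before the data were examined, 28 had at least 5 tested members and were tested against all other tested genes with camera (limma 3.58.1), two-sided, with a preset correlation between genes of 0.01 and adjustment over the lists. The list of mitochondrially encoded genes had no row in the table. Camera with an estimated correlation was an alternative. It refers its statistic to the 2 residual degrees of freedom, so few lists can pass after adjustment, whatever their correlation. Among lists called with the preset, the largest estimates were 0.81 (fibroblast), 0.43 (cell cycle), 0.38 (HOX) and 0.29 (glycolysis). These exceed the preset of 0.01, so the preset p of these lists may be too small. With the estimate, their camera p before adjustment was 0.474, 0.460, 0.483 and 0.411. Fry was run beside it and answers another question, whether the members of a list differ from no change, on balance in 1 direction or in either, without comparison to other genes. Differences between single libraries use log2 CPM after TMM with a prior count of 2.

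The genes to be named were also fixed before the data were examined: LIN28A, the 12 called genes with the largest fold change per direction, up to 3 called members of each list per direction or else the 2 members with the smallest p, every tested DUSP gene, and POU5F1, SOX2 and NANOG. The part for called genes required a mean of at least 1 FPKM, both knockdown libraries on the same side of both control libraries, and a gene symbol. Since no gene was called, that part was replaced, after the values were seen, by the 12 genes per direction with the smallest unadjusted p under the same conditions.

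Alternatives written before the data were examined were DESeq2 size factors, upper-quartile factors or total counts in place of TMM; no expression filter beyond 1 count, or a mean of at least 1 CPM; the DESeq2 1.42.0 Wald test; limma-voom; limma on log2 FPKM plus 1, 0.1 or 0.01; adjusted p thresholds of 0.01 and 0.1; a fold change threshold; leaving out each library; and a block for the last digit of the sample title. Quantile normalisation was planned only for a table without counts and was not run. A covariate made from the ribosomal protein genes, and limma-voom with a weight per library, were added after seeing the data.

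The test was checked on simulated counts for the same 11967 genes with 200 changed genes in each of 10 draws, using the means, library sizes and dispersions of these libraries. It called 4.66% of genes changed by 1 on the log2 scale, 62.2% of those changed by 2, 90.1% of those changed by 3 and 97.6% of those changed by 5. With the dispersions of the 3 libraries without knockdown 2 these were 41.9%, 85.0%, 97.6% and 99.2%. With all 4 libraries, on average 17.6 unchanged genes were called per draw, and 4.79% of unchanged genes had an unadjusted p under 0.05. These false calls were a larger share of all calls than the threshold of 0.05 aims at. Simulated libraries shared the same gene means, without the difference of knockdown 2 from the other libraries. The shares called may therefore not hold for these data, where HMCN1, at a log2 fold change of −3.29, was not called. Of 200 random lists, 0 were called by camera; the simulated genes were independent, so this does not test correlated lists. Figures were drawn with matplotlib 3.10.9 and tables prepared with pandas 2.3.3 under Python 3.11.15. Sequence composition was not examined, because no genome or transcript sequence was used here.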

Results

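Gene expression was measured by RNA sequencing in porcine induced pluripotent stem cells with hairpin RNA against LIN28A, an RNA-binding protein of early embryonic cells that blocks maturation of the let-7 microRNAs, and in negative control cells. Each group had 2 libraries, and the labels do not say whether the 2 knockdown libraries carry the same hairpin, although the deposited table averages them under the part of their names that they share. Summed expected counts were 11847343 in control 1, 7125640 in control 2, 8061417 in knockdown 1 and 2400985 in knockdown 2. Genes with a count above 0 numbered 14747, 14371, 14372 and 13241 in the same order. The series title names DUSP phosphatases, MAPK signalling and pluripotency, so the comparison asks how these gene groups differed when LIN28A was reduced, and gene lists for those subjects are not independent of these libraries.

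LIN28A, on chromosome 6 at 83806178 to 83818550 of Sscrofa11.1, was lower in both knockdown libraries than in both controls. It had 184 counts in control 1 and 59 in control 2, against 12 in knockdown 1 and 3 in knockdown 2. These correspond to 15.5 (95% interval 13.4 to 17.9), 8.28 (6.30 to 10.7), 1.49 (0.769 to 2.60) and 1.25 (0.258 to 3.65) CPM, counts scaled to the library total. Mean FPKM was 24.9 ± 10.9 (SD, n = 2) in the controls and 2.86 ± 0.396 (SD, n = 2) in the knockdown. The edgeR log2 fold change was −2.92 with a standard error of 0.49, and its unadjusted p was 0.00158. Adjusted over all tested genes, the p was 0.259 in edgeR and 0.00855 in DESeq2. Its paralogue LIN28B had 25.1 and 19.0 FPKM in the controls and 13.7 and 10.2 in the knockdown libraries, a log2 fold change of −0.88 ± 0.26 (SE) with an adjusted p of 0.541 in edgeR.

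**Figure D1:**
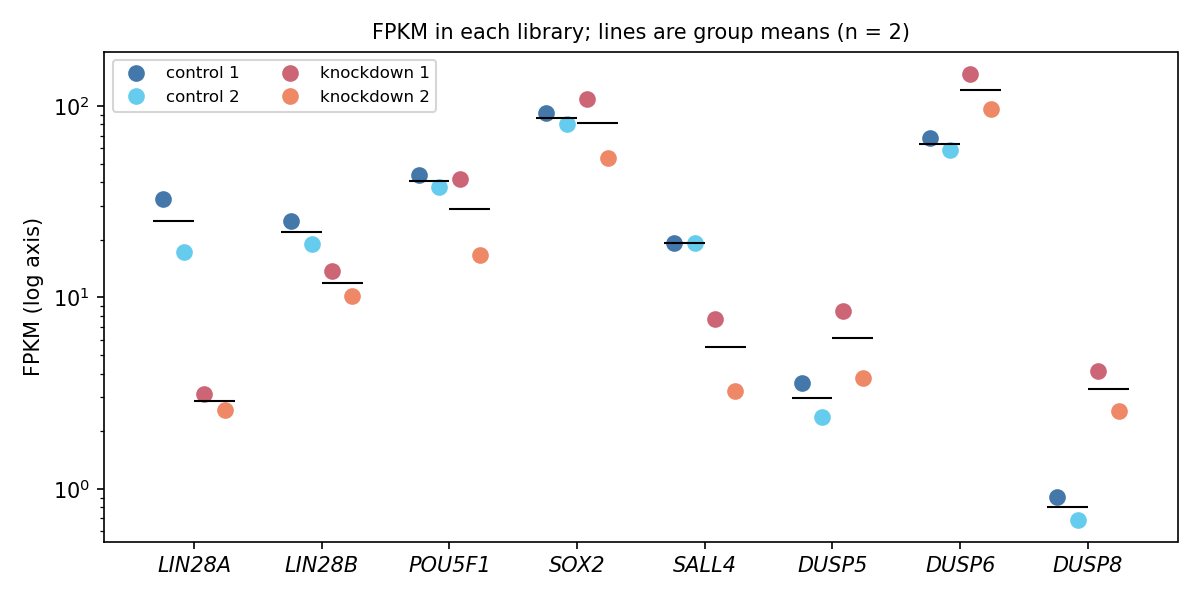
FPKM (log axis) of 8 genes in each of the 4 libraries; points are libraries and short lines are means of the 2 libraries of a group. LIN28A was at 32.6 and 17.2 FPKM in the controls and at 3.14 and 2.58 in the knockdown, and DUSP6 was at 68.0 and 58.7 against 147 and 96.3.

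The MAP kinase phosphatases, dual-specificity enzymes that remove phosphate from MAP kinases, ranked higher in the knockdown than other genes. All 8 tested members had a positive log2 fold change, with a median of 0.82, and in 5 of them both knockdown libraries lay above both controls. Of all tested genes, 41.7% had no overlap between the groups, in either direction. The camera adjusted p was 0.00021, and the adjusted p was 0.558 with an estimated correlation. No member passed the test over all genes; adjusted over the list alone, 3 were higher. DUSP8, which acts on the stress kinases JNK and p38, was at 0.800 ± 0.156 FPKM (SD, n = 2) in the controls and 3.33 ± 1.12 (SD, n = 2) in the knockdown, a log2 fold change of 2.26 ± 0.32 (SE). DUSP6, a feedback phosphatase of ERK, was at 63.4 ± 6.55 against 122 ± 36.0 FPKM (SD, n = 2), a log2 fold change of 1.14 ± 0.24 (SE). DUSP5, a nuclear phosphatase of ERK, was at 2.97 ± 0.834 against 6.13 ± 3.32 FPKM (SD, n = 2), a log2 fold change of 1.24 ± 0.37 (SE). Their adjusted p in edgeR was 0.241, 0.336 and 0.541 over all genes. DUSP10 had a log2 fold change of 1.96 ± 1.03 (SE), but its FPKM was 0.75, 2.90, 2.17 and 9.51 in control 1, control 2, knockdown 1 and knockdown 2. For DUSP1, DUSP4, DUSP7 and DUSP16 the log2 fold changes were 0.50, 0.17, 0.48 and 0.45; that of DUSP4 changed sign when total counts replaced TMM. The median of the list was 0.80 in knockdown 1 and 0.78 in knockdown 2 relative to the control mean, and −0.25 in control 2 relative to control 1. Without knockdown 1 the camera adjusted p was 0.117, with a median of 0.76. Without knockdown 2 it was 1.37e-05, with a median of 0.34 over 9 tested members, and without control 2 it was 0.0226, with a median of 0.47.

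Across the whole DUSP family, 12 of 18 tested members had a positive and 6 a negative log2 fold change, with a median of 0.31. None was called over all genes, and 2, DUSP8 and DUSP6, were higher adjusted over the list alone, which is not independent evidence since the study's title names this family. DESeq2 called both over all genes, with adjusted p of 0.00126 and 0.00505. The camera adjusted p of the family was 0.0301, against an adjusted p of 0.558 with an estimated correlation, and the same 8 MAP kinase phosphatases are among its members. The call was lost without control 2 (0.198, median 0.06) and without knockdown 1 (0.539, median 0.23). The median was 0.16 without knockdown 2 and 0.10 with total counts. The lowest value belonged to DUSP23 at −0.62, followed by DUSP18 at −0.43 and DUSP11 at −0.29. DUSP12, DUSP14, DUSP19, DUSP28 and STYXL1 lay between −0.14 and 0.11, and DUSP3 and STYX were at 0.51 and 0.46; the signs of DUSP14 and DUSP28 changed with total counts, that of DUSP28 also with upper-quartile factors, and those of DUSP19 and STYXL1 with DESeq2 size factors.

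**Figure D2:**
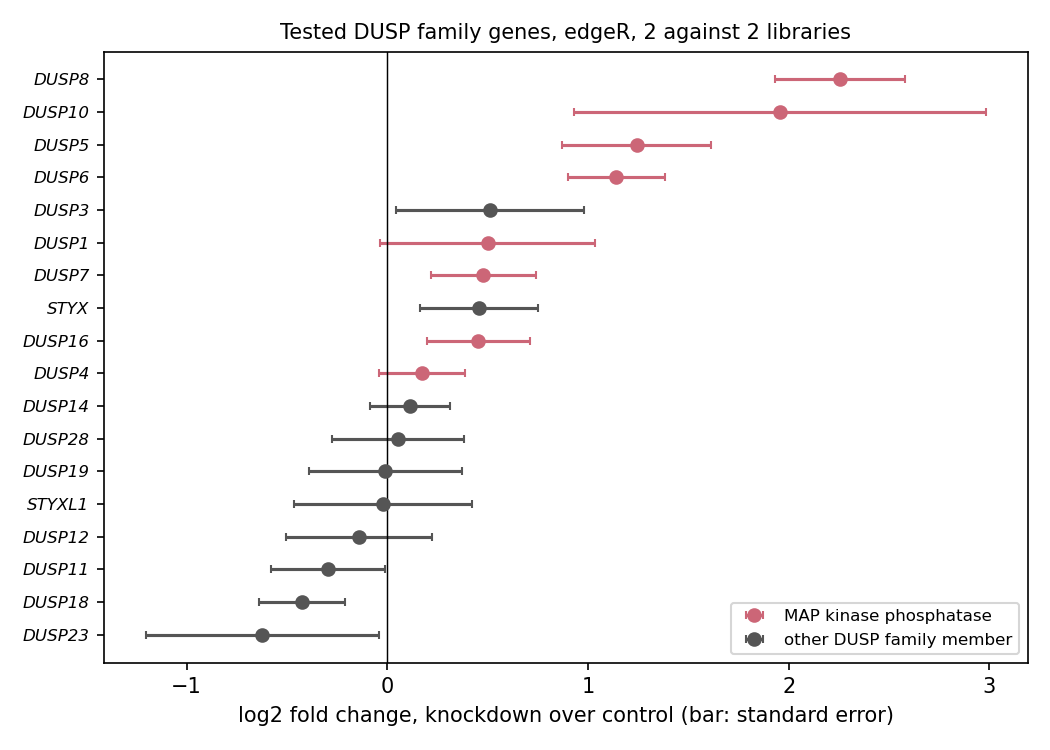
Log2 fold change of knockdown over control for the 18 tested DUSP family genes, from edgeR on 2 against 2 libraries; bars are standard errors. All 8 MAP kinase phosphatases lie above 0, from DUSP4 at 0.17 to DUSP8 at 2.26, while the other members lie on both sides.

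Genes that ERK signalling induces and its feedback genes, listed without the DUSPs, also ranked higher (median log2 fold change 0.53, 28 of 37 positive, camera adjusted p 0.0235), and the adjusted p was 0.558 with an estimated correlation. No member was called. IER5, an immediate early gene, was at 37.1 and 37.0 FPKM in the controls and 74.6 and 52.4 in the knockdown, while FGFBP3, an FGF-binding protein in the same list, was at 2.88 and 3.46 against 0.32 and 0. The call was lost without control 2 (0.118, median 0.33) and without knockdown 1 (0.117, median 0.28), and the median was 0.25 without knockdown 2. Kinases and adaptors of the MAPK cascade had a median of 0.24 with 38 of 51 positive and a camera adjusted p of 0.0691, and this median was −0.01 with total counts. The list was called higher without knockdown 1 (0.0218, median 0.43), with every gene of at least 1 count (0.0302, median 0.23) and on log2 FPKM plus 1 (0.0408, median 0.05). Of that list, MAPK4 had a log2 fold change of −0.71 and MAP2K7, a kinase of JNK, one of 0.81. FGF ligands and receptors had a camera adjusted p of 0.709, with FGFR3 at −2.01 and FGF11 at −0.47. A list of WNT pathway genes had a camera adjusted p of 0.558, with RNF43 at 1.12 and APCDD1 at −0.99.

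Among the core pluripotency genes, SALL4 alone passed a test, adjusted over the list. POU5F1 was at 43.4 and 37.7 FPKM in the controls and 41.4 and 16.6 in the knockdown libraries, a log2 fold change of −0.29 ± 0.31 (SE). SOX2 was at 91.9 and 80.9 against 109 and 53.5 FPKM, a log2 fold change of 0.09 ± 0.26 (SE) whose sign changed with total counts. NANOG was present as 2 gene entries, and neither exceeded 0.70 FPKM or 7 counts in any library, too few to be tested. SALL4, a zinc finger factor of pluripotent cells, was at 19.2 and 19.2 FPKM in the controls and 7.71 and 3.25 in the knockdown, a log2 fold change of −1.62 ± 0.31 (SE); it had an edgeR adjusted p of 0.301 over all genes and was lower adjusted over the list alone. KLF4 had a log2 fold change of 1.24. The 12 tested members of this list split into 6 positive and 6 negative (camera adjusted p 0.556). Genes of the primed state had a median of −0.03 and a camera direction that was upward, with an adjusted p of 0.537. Adjusted over that list alone, POU3F1, a POU factor of epiblast and neural cells, was higher (1.61 against 7.96 FPKM), as was DUSP6, and THY1 was lower (8.84 against 4.59 FPKM). Their edgeR adjusted p over all genes was 0.243, 0.336 and 0.336.

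Targets of let-7, whose maturation LIN28A blocks, did not pass the list test. Of 64 tested members, 33 were positive and 31 negative, with a median of 0.01 that turned negative with upper-quartile factors or total counts, while the camera direction was downward with an adjusted p of 0.139. At an unadjusted edgeR p under 0.05, 11 were lower and 1 was higher, where 413 of all 11967 tested genes were lower and 510 higher. PRTG, a cell surface protein of the early neural tube, was at 31.5 ± 6.61 FPKM in the controls and 8.65 ± 3.16 in the knockdown (SD, n = 2). NR6A1, a nuclear receptor of early embryos, was at 13.0 ± 4.69 against 3.46 ± 1.44 FPKM (SD, n = 2). Their edgeR adjusted p was 0.259 and 0.287. The let-7 microRNAs themselves were not measured in these libraries. The list of LIN28 and small RNA pathway genes had a camera adjusted p of 0.709, with MSI2, an RNA-binding protein, at a log2 fold change of 0.69.

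Lineage lists differed in direction. The ectoderm and neural list ranked higher (camera adjusted p 0.0386, and an adjusted p of 0.558 with an estimated correlation). Its median of 0.16 became −0.04 with total counts, 16 of 24 members were positive, and the call was lost without control 1 (0.141), control 2 (0.0797) or knockdown 1 (0.539), where the medians were 0.40, 0.39 and 0.09. Without knockdown 2 the camera adjusted p was 2.22e-05, with a median of 0.26. Adjusted over the list alone, NEUROD4, a proneural factor, was higher (2.44 against 9.71 FPKM), as was DCX, a microtubule protein of migrating neurons (6.62 against 16.3 FPKM). Over all genes their edgeR adjusted p was 0.219 and 0.327. The endoderm list ranked lower, with 10 of 13 members negative and a median of −0.49 (camera adjusted p 0.00295, and an adjusted p of 0.558 with an estimated correlation). Adjusted over the list alone, the basement membrane collagen COL4A2 (9.65 and 12.5 against 1.82 and 2.77 FPKM) and the apolipoprotein APOA1 (64.2 against 20.8 FPKM) were lower. For these 2 genes the edgeR adjusted p over all genes was 0.278 and 0.371. The next values are again those of the endoderm list. Its camera adjusted p was 0.179 without control 2 (median −0.22), 0.562 without knockdown 1 (median −0.43) and 1.89e-08 without knockdown 2 (median −0.49). The trophectoderm list also ranked lower, at a median of −0.51 (camera adjusted p 0.0235, and an adjusted p of 0.592 with an estimated correlation), with 6 of 11 members negative. The keratins KRT8 (14.5 and 38.9 against 1.11 and 1.85 FPKM) and KRT18 (2.22 and 4.32 against 0.29 and 0 FPKM) were its lower members adjusted over the list alone. Over all genes the edgeR adjusted p was 0.263 for KRT8 and 0.364 for KRT18. That list's call was lost without control 2 (0.198) and knockdown 1 (0.539, median −1.14), and its median was 0.08 without control 1 and −0.24 without knockdown 2. The mesoderm list had a median of 0.55 and a camera adjusted p of 0.114, with ACTC1 at 1.13 and FOXC1 at 1.27. In the list of epithelial and mesenchymal adhesion genes the median was 0.10, which turned negative with upper-quartile factors or total counts, and the camera direction was downward with an adjusted p of 0.139; KRT8 was lower adjusted over that list alone.

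Growth and stress lists were tested in the same way. Cell cycle and replication genes ranked lower, with 43 of 52 negative and a median of −0.28 (camera adjusted p 0.00295, and an adjusted p of 0.684 with an estimated correlation). The median was −0.12 in knockdown 1 and −0.37 in knockdown 2, and the camera adjusted p was 0.0914 without knockdown 2, where the median was −0.15. CCNB1, the mitotic cyclin, was at 123 ± 1.82 FPKM in the controls and 69.9 ± 32.9 in the knockdown (SD, n = 2), and CENPA, a centromeric histone, was at 36.1 against 23.1. Glycolysis genes ranked lower at a median of −0.35, with 19 of 26 negative (camera adjusted p 0.0235, and an adjusted p of 0.684 with an estimated correlation). This list was also lower in control 2 than in control 1, with a median difference of −0.43, and its camera adjusted p was 0.506 without control 1, where the median was −0.11. Its median was −0.65 without knockdown 1 and −0.21 without knockdown 2. LDHA, lactate dehydrogenase, was at 958, 680, 502 and 230 FPKM in control 1, control 2, knockdown 1 and knockdown 2, and ALDOC, an aldolase, had a log2 fold change of −0.72. Targets of p53 and cell cycle inhibitors ranked higher (median 0.24, 22 of 29 positive, camera adjusted p 0.0235, and an adjusted p of 0.684 with an estimated correlation); PHLDA3 was at 16.2 and 16.9 against 29.2 and 30.3 FPKM, and PLK2 at 52.3 and 41.7 against 82.0 and 104. Genes of the ATF4 and unfolded protein response ranked higher (median 0.49, 21 of 27 positive, camera adjusted p 0.0224, and an adjusted p of 0.592 with an estimated correlation), with SLC7A11 at a log2 fold change of 0.88 and DNAJB9 at 1.03. The calls of both lists were lost without control 2 (0.176 and 0.183) and without knockdown 1 (0.570 and 0.221). The p53 median was 0.10 without knockdown 1, 0.45 without control 1, 0.38 without knockdown 2 and 0.06 with total counts. The ATF4 median was 0.12 without knockdown 1, 0.27 without control 2, 0.80 without control 1 and 0.30 with total counts. Genes of the TGF-beta, NODAL and BMP pathway ranked higher, with 26 of 33 positive and a median of 0.56 (camera adjusted p 0.00295, and an adjusted p of 0.558 with an estimated correlation). This call remained past the threshold without each library in turn, but the median was 0.14 without knockdown 2, against 0.41 to 0.52 without any other library, and 0.16 with a covariate made from the ribosomal protein genes. Relative to the control mean it was 0.19 in knockdown 1 and 0.54 in knockdown 2, the library in which the fibroblast list was also highest. TGFBI, a matrix protein induced by TGF-beta, was at 5.28 and 7.62 against 15.3 and 19.0 FPKM, and ID3, an inhibitor of differentiation induced by BMP, at 178 and 163 against 368 and 182.

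Markers of other cell types differed within groups as well as between them. The fibroblast list ranked higher in the knockdown (median 1.09, 24 of 27 positive, camera adjusted p 0.00295, and an adjusted p of 0.684 with an estimated correlation). Relative to the control mean its median was −0.12 in knockdown 1 and 1.78 in knockdown 2, and it was 0.87 higher in control 2 than in control 1. Without knockdown 2 the median was −0.20 and the camera adjusted p was 0.312. THY1 and COL6A2 had the smallest p in this list, in opposite directions. COL6A2 was at 1.19, 2.47, 3.29 and 8.24 FPKM in control 1, control 2, knockdown 1 and knockdown 2. THY1 was at 9.79, 7.89, 3.38 and 5.80 FPKM in the same order, a log2 fold change of −1.17. The HOX genes ranked higher as well (median 0.57, 21 of 26 positive, camera adjusted p 0.0301, and an adjusted p of 0.684 with an estimated correlation). Their median was −0.22 in knockdown 1 and 1.02 in knockdown 2 relative to the control mean, and 1.89 higher in control 2 than in control 1. The HOX call was lost without control 1 (0.433), knockdown 1 (0.0506) or knockdown 2 (0.891), where the median was −0.50. HOXA2 and HOXD10 had the smallest p in this list, with log2 fold changes of 0.58 and 1.82. The blood cell list had 6 tested members and a camera adjusted p of 0.233, and its median was also 1.97 higher in knockdown 2 than in knockdown 1; CORO1A and SPI1 had log2 fold changes of 1.77 and 1.64.

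**Figure D3:**
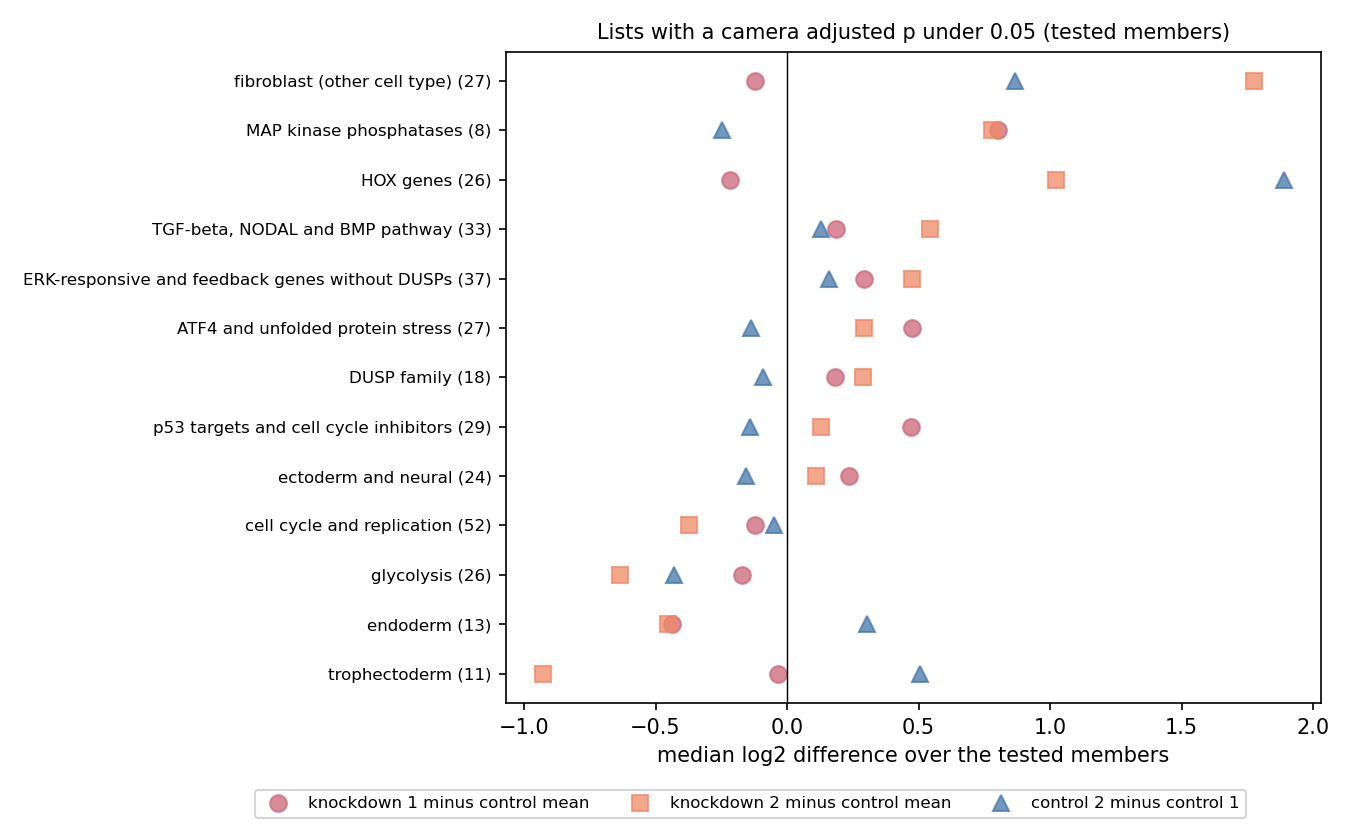
Median log2 difference over the tested members of the 13 lists with a camera adjusted p under 0.05: each knockdown library against the control mean, and control 2 against control 1. The MAP kinase phosphatases were at 0.80 and 0.78 in the knockdown libraries and at −0.25 between the controls, whereas the fibroblast list was at −0.12 and 1.78 in the knockdown libraries and at 0.87 between the controls.

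The remaining lists did not pass the test. Camera adjusted p was 0.358 for interferon response genes, of which MX1 and ISG15 had log2 fold changes of 0.93 and 1.63. It was 0.519 for heat shock genes (CRYAB 1.87, HSPA8 0.72), 0.438 for DNA and histone modifiers (KAT2A 0.87, SUV39H1 0.52), and 0.358 for nuclear-encoded oxidative phosphorylation genes (NDUFA8 0.40). The cytosolic ribosomal proteins had an adjusted p of 0.450, with RPL26 at −0.62 and RPS29 at −0.56, and were called lower without knockdown 2 (0.00667, median −0.15). Between the knockdown libraries these 77 genes differed by −0.50 for RPS7 to 2.03 for RPL37A (log2), with an SD of 0.71, against an SD of 0.20 between the controls, and across genes the 2 differences correlated at r = 0.90. Fry tests a list against no change and not against other genes. With it, no list passed the directional test (smallest adjusted p 0.0901), and 2 passed the test for change in either direction: the ectoderm and neural list (0.000118) and the DUSP family (0.00314).

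**Figure D4:**
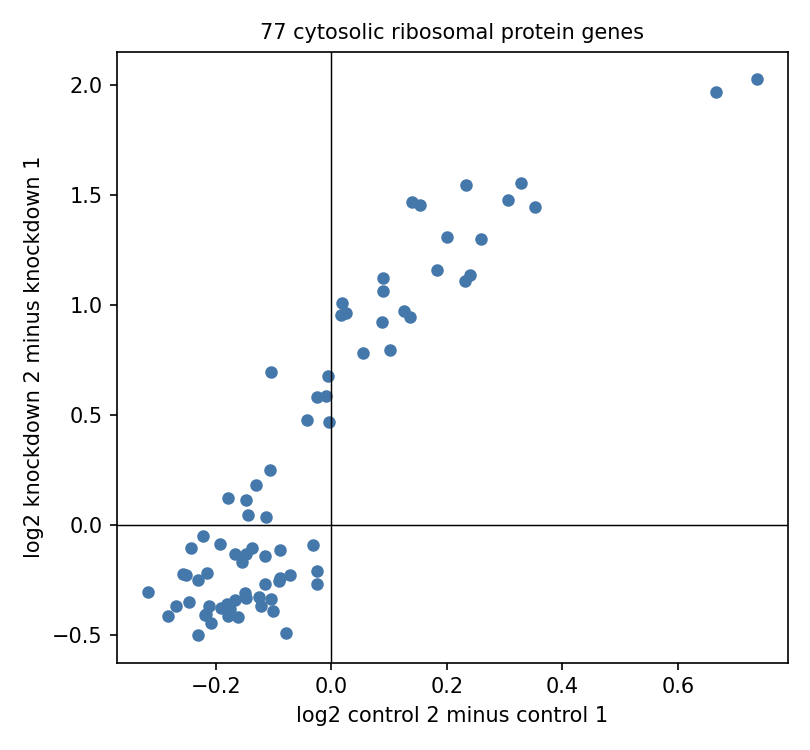
Log2 difference between the 2 knockdown libraries against that between the 2 controls for 77 cytosolic ribosomal protein genes, 1 point per gene. The axes have different scales, and 42 genes were lower and 35 higher in knockdown 2 than in knockdown 1.

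Over single genes, edgeR called 0 higher and 0 lower of 11967 tested, the smallest adjusted p being 0.144. At an unadjusted p under 0.05 there were 510 with a positive and 413 with a negative log2 fold change, where 598 in all would be given by uniform p-values. These libraries depart from that: splitting them by title digit instead gave 640 such genes. The split of control 1 and knockdown 2 against control 2 and knockdown 1 gave 9. DESeq2 called 104 higher and 35 lower, limma-voom called 0 and 0, and limma on log2 FPKM plus 1 called 14 and 17. Without knockdown 1 edgeR called 1110 higher and 94 lower, and without knockdown 2 it called 7 and 4. Knockdown 2 had the fewest counts and stood apart from the other libraries: across 11096 genes its log2 of FPKM plus 1 correlated with that of knockdown 1 at r = 0.926, with that of control 2 at 0.932 and with that of control 1 at 0.886, while the controls correlated with each other at 0.977 and with knockdown 1 at 0.972 and 0.971. These correlations are across genes, which are not independent replicates.

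The genes with the smallest unadjusted p in each direction were also examined. None of those named next passed the edgeR threshold, and they were chosen after their values were seen. On the higher side, CNTN2, an axonal adhesion protein, was at 6.78 and 6.78 FPKM in the controls and 39.5 and 25.1 in the knockdown, a log2 fold change of 2.45 ± 0.23 (SE). The proneural factor ATOH1 was at 6.87 ± 1.60 against 28.8 ± 12.4 FPKM (SD, n = 2), and NHLH2, another basic helix-loop-helix factor, at 0.17 and 0.33 against 4.35 and 3.52. BCL11A, a transcriptional repressor, was at 2.86 and 3.80 against 26.1 and 14.4 FPKM, and CAMK2A, a calcium-dependent kinase, at 1.62 and 1.84 against 7.25 and 5.94. NEUROD4, RASD2, LRRC4B, DISP3, MMP17, GSE1 and CHST15 complete the 12, with log2 fold changes between 1.61 for CHST15 and 3.92 for RASD2.

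On the lower side, HMCN1, an extracellular matrix protein on chromosome 9 at 126850208 to 127342696, had the smallest p of all tested genes. It was at 5.73 and 5.33 FPKM in the controls and 0.56 and 0.41 in the knockdown, a log2 fold change of −3.29 ± 0.21 (SE) with an edgeR adjusted p of 0.144. NELL2, a secreted protein of neural cells on chromosome 5, was at 52.6 and 63.9 against 7.50 and 4.79 FPKM. PDPN, a membrane mucin, was at 11.5 and 11.2 against 2.30 and 1.46 FPKM, CDH6, a cadherin, at 44.3 and 43.1 against 13.5 and 12.1, and NID2, a basement membrane protein, at 5.51 and 6.17 against 1.42 and 1.49. PAX5 was at 5.79 and 7.27 against 1.14 and 1.43 FPKM. BID, a pro-apoptotic BCL2 family member on chromosome 5 at 69849007 to 69874647, had 105 and 79 counts in the controls and 0 in both knockdown libraries, which makes it at least 33.8-fold lower with a floor of 3 counts over the 2 libraries. The other 5 of these genes were TRIM4, SUMF1, SLITRK2, GREB1L and GABRG3, with log2 fold changes between −1.64 for GREB1L and −4.08 for TRIM4.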

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

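The covariate from the ribosomal protein genes and limma-voom with library weights were chosen after seeing the data; the other settings were not. LIN28A kept its direction and an unadjusted p under 0.05 under every alternative, with log2 fold changes from −2.41 without control 1 to −3.28 without control 2 when a library was left out and from −2.69 to −3.08 otherwise. The 0 higher and 0 lower genes became 2 and 6 with total counts in place of TMM, 28 and 12 with every gene that had at least 1 count, 104 and 35 with DESeq2, 49 and 15 with the ribosomal covariate, and 14 and 17, 8 and 10, and 6 and 8 with limma on log2 FPKM plus 1, 0.1 and 0.01. Leaving out 1 library gave 0 to 1110 higher and 0 to 94 lower genes, the most without knockdown 1; there the lone library is assumed to vary like the other group. Other factors, filters and thresholds and limma-voom gave 0. The cause was not tested.

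Total counts moved the median log2 fold change of all genes from 0.01 to −0.18 and the FPKM scale to between −0.19 and −0.22; of genes with an unadjusted p under 0.05, 55.3% were positive with TMM, 54.0% with total counts and 37.0% with log2 FPKM plus 1. DUSP family genes called higher over all genes went from 0 to 2 with DESeq2 and 1 with the ribosomal covariate, and ranged from 0 to 1 with a library left out. Adjusted over the list alone, the 2 higher became 1 with upper-quartile factors, total counts or log2 FPKM plus 1, and 0 with a pseudocount of 0.1 or 0.01 or a threshold of 0.01; leaving out a library gave 0 to 3. The 13 lists called by camera became 0 with an estimated correlation, 8 with library weights and 5 at a threshold of 0.01, and 5 to 12 with a library left out, against 14 with total counts and 15, 15 and 14 with log2 FPKM plus 1, 0.1 and 0.01. Fry, a test against no change, passed 0 lists in its directional and 2 in its mixed form. The MAP kinase phosphatase median of 0.82 stayed past the camera threshold except with an estimated correlation (adjusted p 0.558) and without knockdown 1; with a library left out it ranged from 0.34 to 1.21. Fry gave this list 0.0901 (directional) and 0.0538 (mixed).

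With all 4 libraries, these camera calls were also lost (adjusted p, median). Ectoderm and neural: DESeq2 size factors (0.0524, 0.19), the replicate block (0.0704, 0.19), limma-voom (0.0521, 0.22), library weights (0.0750, 0.28) and log2 FPKM (0.0871 to 0.0911). Trophectoderm: every gene (0.390, −0.02), mean of 1 CPM (0.0819, −0.22), limma-voom (0.179, −0.32) and library weights (0.562, −0.48). HOX: limma-voom (0.189, 0.52), library weights (0.127, 0.68) and the ribosomal covariate (0.560, −0.57). ERK-responsive genes: limma-voom (0.0653, 0.41) and library weights (0.0888, 0.51). DUSP family and endoderm: every gene (0.0836, 0.12, and 0.0777, −0.34). ATF4: library weights (0.0708, 0.46). Cell cycle, glycolysis and fibroblast: the ribosomal covariate (0.133, −0.11; 0.0785, −0.15; and 0.0785, −0.19). Calls were gained for the MAPK cascade and mesoderm (every gene, both 0.0302, and each FPKM scale, 0.0394 to 0.0408 and 0.0247 to 0.0261) and blood cell (total counts 0.0453), and for ribosomal proteins with the covariate (0.00511).

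For 5 lists the median changed sign with the list called either with TMM and all libraries or under the alternative. The ectoderm and neural median was −0.0380 with total counts and −0.0311, −0.0330 and −0.0333 with log2 FPKM plus 1, 0.1 and 0.01. With a library left out, the trophectoderm median ranged from −1.14 to 0.0766 (without control 1). The fibroblast median ranged from −0.20 without knockdown 2 to 1.72 without knockdown 1, and was −0.19 with the ribosomal covariate. The HOX median ranged from −0.50 without knockdown 2 to 2.13 without control 2, and was −0.57 with the covariate. The median of epithelial and mesenchymal adhesion genes, not called with all libraries and TMM, ranged from −0.44 without knockdown 2 to 0.16 without control 1, and was −0.28 with the covariate and −0.12 with log2 FPKM plus 1 or 0.1. The list was called lower in these 5 settings. Medians of 13 more lists changed sign under at least 1 alternative with the list called in neither: mesoderm, blood cell and MAPK cascade (−0.07, −0.09 and −0.05 without knockdown 2), FGF, WNT, let-7 targets, LIN28 pathway, core and primed pluripotency, oxidative phosphorylation, interferon, heat shock, and DNA and histone modifiers. Of 1831 values for the 92 named genes other than LIN28A, 1562 kept their sign and their side of the threshold, 233 passed it only under the alternative, and 36 changed sign without passing it in either.

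No label pairs the library numbers. Across 9653 genes, the difference between the controls correlated with that between the knockdown libraries at r = 0.62, and with the replicate block edgeR, left with 1 residual degree of freedom, called 1032 higher and 306 lower genes, LIN28A (adjusted p 4.31e-09) and 4 DUSP family genes, over all genes or the list alone.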

Other observations

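The tests of thinned counts were written before their result was seen; the other tests here, and the genes named, were chosen after the values were seen. Some genes known from the developing neural tube were expressed in all 4 libraries. CRABP1, a retinoic acid-binding protein, was at 3003 and 2005 FPKM in the controls and 2797 and 2875 in the knockdown. EN2, a midbrain and hindbrain factor, was at 89.4 and 130 against 119 and 78.8, ZIC2 at 276 and 252 against 302 and 155, PAX7 at 24.2 and 15.5 against 24.2 and 13.2, and HOXA2 at 26.6 and 26.2 against 42.0 and 26.7. EN1, a paralogue of EN2, was at a mean of 0.615 FPKM in the controls and 1.83 in the knockdown. OTX2, a forebrain and midbrain factor, did not exceed 0.16 FPKM in any library, and the epithelial genes CDH1 and EPCAM were at most 1.09 and 3.42 FPKM in the controls and 0.10 and 0.68 in the knockdown. DCC, an axon guidance receptor, was at 4.61 and 4.65 FPKM in the controls and 15.7 and 9.87 in the knockdown.

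A few genes were present in 1 group and at 0 in both libraries of the other. With at least 50 pooled counts in the group that expressed them, 1 gene was at 0 in both controls and 3 were at 0 in both knockdown libraries. FCRL5, an Fc receptor-like gene of B cells on chromosome 4 at 92578672 to 92631713, had 0 counts in both controls and 570 and 45 in knockdown 1 and 2, at least 372-fold higher with a floor of 3 counts over the 2 control libraries. The 3 others were BID, EMP1, with 22 and 58 counts in the controls, and DCN, with 49 and 2.

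Control 2 lay close to the libraries numbered 1 (r = 0.977 with control 1 and 0.971 with knockdown 1, on log2 of FPKM plus 1). Knockdown 2 stood apart from the other libraries. Shallow sequencing is not enough to account for this: with the other 3 libraries thinned to the total of knockdown 2, it still differed from knockdown 1 by a root-mean-square log2 difference of 0.829 (mean of 20 draws), against 0.488 to 0.549 among the other 3. As the whole source, the knockdown is argued against by the correlation of 0.62 across genes between control 2 minus control 1 and knockdown 2 minus knockdown 1. By the same measure, knockdown 1 minus control 1 correlated with knockdown 2 minus control 2 at 0.57. The main axis of variation over these genes, with 77.2% of the variance, placed control 1 at −34.3 and control 2 at −9.31. Knockdown 1 was at −11.3 on it and knockdown 2 at 55.0. Both differences are positive on this axis between libraries, so the 0.57 cannot show that a difference between groups repeated. With the numbers crossed, knockdown 1 minus control 2 correlated with knockdown 2 minus control 1 at −0.03. RNA from other cells remains a candidate explanation: the fibroblast list was 0.867 higher in control 2 than in control 1 and 1.85 higher in knockdown 2 than in knockdown 1 (median log2), with COL1A1 at 17.6, 52.8, 56.5 and 206 FPKM and TWIST2 at 10.7, 58.9, 39.7 and 260 in control 1, control 2, knockdown 1 and knockdown 2, although the fibroblast genes DCN, LUM and COL6A3 had 0 counts in knockdown 2. The ribosomal proteins moved apart, from −0.50 for RPS7 to 2.03 for RPL37A between the knockdown libraries (SD 0.71 over 77 genes, against 0.19 between knockdown 1 and control 1), which cells of another species, with only conserved transcripts matching the pig, might give; this cannot be told apart from other sources without reads or sequence.

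As a median, the higher rank of the MAP kinase phosphatases did not follow that difference between libraries. The median of the 8 tested members was 0.99 higher in knockdown 1 than in control 2 on the log2 scale. It was −0.25 for control 2 minus control 1 and −0.18 for knockdown 2 minus knockdown 1. RNA from other cells rich in these transcripts would raise it there, and RNA poor in them would lower it. Single members varied: these differences were 1.89 and 2.49 for DUSP10 and −1.15 and −1.23 for DUSP1. They were −0.52 and −0.72 for DUSP5. For DUSP8 and DUSP6 both were also negative, and for DUSP4, DUSP7 and DUSP16 the signs differed. Knockdown 2 alone is also not the source, since the camera adjusted p was 1.37e-05 without it, although the median was then 0.34 over 9 tested members, against 0.82 over 8 with all libraries, and the adjusted p was 0.117 without knockdown 1, with a median of 0.76. A response to the knockdown stays open as a hypothesis that 2 libraries per group cannot separate from differences between cultures. With an estimated correlation, which was −0.0292 for this list, the camera p was 0.0435 before and 0.558 after adjustment over the lists. That version uses only 2 residual degrees of freedom, so it has little power whatever the correlation.

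The higher rank of the fibroblast and HOX lists in the knockdown may come from the same source as the difference between libraries. The HOX median was 1.89 higher in control 2 than in control 1 (log2), and 0.81 lower in knockdown 1 than in control 2; HOXC8 was at 2.87, 23.3, 3.26 and 51.2 FPKM in control 1, control 2, knockdown 1 and knockdown 2. The fibroblast median was −0.40 in knockdown 1 relative to control 2. Relative to control 1, however, knockdown 1 was 0.69 higher for HOX genes and 0.29 higher for the fibroblast list, so the direction in knockdown 1 depends on the control it is compared with.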
